A study of Mus musculus with 12 samples.

How the data were processed

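Gene expression was measured in mouse CD4+ T cells of the C57BL/6 strain on 12 one-colour Agilent 4x44K arrays, 3 for each of 4 culture conditions. Per the labels' protocols, naive CD4+ T cells were taken from spleen and lymph nodes by magnetic selection, activated through CD3 and CD28, cultured for 5 days and expanded on day 3. Th2 cultures received IL-4 at 20 ng/ml and an antibody against IFN-γ. Th9 cultures received the same together with TGF-β at 2 ng/ml. Regulatory T cell (Treg) cultures received TGF-β at 2 ng/ml, an antibody against IL-4 and, at expansion, IL-2. Stimulated Th9 cultures were Th9 cultures exposed on day 5 to anti-CD3 at 1 µg/ml for 6 h. Per the labels, 0.5 µg of total RNA was amplified and labelled with Cy3. Arrays were placed in groups and numbered from the sample titles. The labels do not say whether arrays of one group came from separate cultures or animals, so p-values measure only the spread between these samples, which may be technical.

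The scanner output gives spot intensity on a linear scale, made with Agilent Feature Extraction 10.5.1.1 per the file headers, with background subtraction and spatial detrending within each array and no normalization between arrays. Each array has 45018 spots, of which 43379 are not controls and represent 41174 probes. A second deposited table per array holds intensity values that equal the mean processed signal of each probe's spots (median ratio 1), as comparison of the values showed. The deposited table of the whole series holds log2 values that were quantile normalized between arrays, as judged from the values: each of its 12 columns correlated with log2 of the same array's processed signal at 0.9996 or above, and the column medians lay between 5.171 and 5.174. The tool behind that table, its offset and any statistical test run by the authors are not given in the sources used here, and 83 of its values were missing.

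From the scanner output, log2 of the processed signal was taken and the 75th percentile of each array was subtracted, so that a level is a log2 signal relative to that percentile. Control spots and spots with an outlier flag (60 to 94 per array) were left out and the spots of a probe were averaged. No probe was saturated. A probe was kept when it was well above background, in the scanner software's own call, on at least 3 of the 12 arrays, and a gene was represented by its probe with the highest mean. Probe names came from RefSeq accessions for 24375 probes, from current symbols for 6301 and from older symbols for 2426, through a GRCm38.p6 gene table, while 8072 kept the name of the array design. The array design was annotated on another genome build, mm8, so no coordinates are given. This left 17925 genes, 14208 of them named through the gene table. Of 6240 genes with several probes, 4 had probes called in opposite directions between Th9 and Th2, 478 between Th9 and Treg, 260 after stimulation and 534 between Th2 and Treg. Probes of near-identical genes (Ifit3 and Ifit3b, Lyz1 and Lyz2, Ifi203 and Ifi204, Serpina3f) may bind each other's transcripts, and these genes are uncertain.

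All 12 arrays were fitted together with limma 3.58.1 (lmFit with 1 mean per group, then eBayes) in R 4.3.3, with the packages data.table (version 1.17.8) and jsonlite (version 2.0.0). The fit had 8 residual degrees of freedom and a prior of 2.51. P-values were adjusted by the Benjamini-Hochberg method within each comparison, and a gene was called at an adjusted p under 0.05. Errors of log2 differences are limma standard errors (SE), errors of levels are standard deviations (SD), and n is 3 arrays per group throughout. Where a probe was not well above background on any array of the dimmer group, the fold is a bound, written as at least N-fold. It sets the brighter group's mean against the mean, over the dimmer group's arrays, of the higher of the probe's own signal and the lowest signal among probes well above background on that array.

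The comparisons, the alternatives and 22 gene lists (364 genes, 359 on the array and 342 tested, 63 in more than 1 list) were fixed before the data were examined, except the alternative that leaves out the arrays numbered 3, which was chosen after the data were seen. The rule for named genes was fixed before. It takes, per comparison, the 8 largest increases and the 8 largest decreases among called genes whose arrays do not overlap between groups, whose probe is well above background on all 3 arrays of the brighter group and that carry a gene symbol. It adds the 8 genes with the largest smaller change among those higher, and among those lower, in Th9 than in both other cultures, and up to 4 called members of each list with the largest change. It also takes Il9, Il4, Il5, Il13, Il10, Gata3, Spi1, Irf4, Batf and Foxp3 whatever their result. The probe of Spi1 was well above background on 2 of the 12 arrays and was not tested. Only some of the genes this rule gave are reported here. Lists were tested with limma's camera against all other tested genes, with a preset correlation of 0.01 between members and again with the correlation estimated from the residuals. No list passed the threshold in any comparison with the estimated correlation. The median, the mean and the test of a list differed in sign for Treg genes, homing receptors and mast cell markers between Th9 and Th2, for ribosome biogenesis genes between Th9 and Treg, for Treg genes and pan T cell markers after stimulation, and for Th17 genes and the CD8 T cell and NK cell markers between Th2 and Treg. None of these list results passed the threshold.

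The arrays lie on 3 slides. Slide 1 holds the 3 Th2 arrays and Treg array 1. Slide 2 holds Treg arrays 2 and 3 and stimulated arrays 1 and 2. Slide 3 holds the 3 Th9 arrays and stimulated array 3. A fit with the slide as a fixed block was run as an alternative. Because that fit has as many terms as there are combinations of group and slide, its value for stimulated against unstimulated Th9 is the difference within slide 3 and its value for Th2 against Treg is the difference within slide 1. In each of these 1 of the groups has a single array, which is assumed to vary like the arrays of the other groups. Th9 shares no slide with Th2 or Treg, so there the blocked value is a chain of differences across slides with larger errors. Same-numbered Th9 and Th2 arrays deviated together from their group means (correlations 0.201, 0.185 and 0.411 over genes), so the numbers were taken to pair those arrays, as a property of the data that no label states. The main fit does not use this pairing, and its p-values are unpaired. With the replicate number as a block, 2727 of the 3049 genes called between Th9 and Th2 were called in the same direction.

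Other alternatives were normexp background correction, quantile and median scaling, other filters and probe summaries, a random slide block, a replicate block, only the arrays compared, an intensity trend with robust settings, stricter thresholds, the deposited log2 table and the omission of each array in turn. The steps were tested on simulated data with 17925 genes. For Th9 against Th2, 26% of genes changed 1.5-fold, 61.3% of those changed 2-fold and 96% of those changed 4-fold were recovered, with 7 false calls. For Th9 against Treg the shares were 20%, 65.3% and 96%, with 9 false calls. In the simulated data few genes were changed, only in Th9, and the noise was independent, with no slide or number effect. The real comparisons called many more genes, so these shares and false calls need not hold there. The number of arrays limits the precision: the median SE of a log2 difference was 0.166.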

Results

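The transcriptomes of Th9 cells, the helper T cells that make IL-9, were measured beside those of Th2 and Treg cells, together with Th9 cells restimulated through the T cell receptor (TCR). Each of the 4 groups had 3 arrays. Between 24642 and 26216 probes per array (59.8 to 63.7%) were well above background, and the 75th percentile of the signal lay between 521 and 796. Over genes, arrays of one group correlated with each other at 0.988 to 0.995. The first principal component held 52.6% of the variance and the second 32.3%.

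Il9 separated Th9 cells from the other unstimulated cultures, and Foxp3 differed between all 3 of them. Il9, the signature cytokine gene of Th9 cells, had a mean level of -1.69 ± 0.66 (SD, n = 3) in Th9 cells, -8.08 ± 0.09 in Th2 cells and -7.76 ± 0.36 in Treg cells. Its probe was not well above background on any Th2 or Treg array. It was at least 18.1-fold higher in Th9 than in Th2 cells (adjusted p = 4.19e-06) and at least 19.6-fold higher than in Treg cells (adjusted p = 1.94e-07). Foxp3, the transcription factor gene of Treg cells, was highest in Treg cells (0.57 ± 0.19), intermediate in Th9 cells (-1.98 ± 0.09) and not well above background in Th2 cells. It was at least 14.0-fold higher in Th9 than in Th2 cells (adjusted p = 4.01e-06) and lower in Th9 than in Treg cells, with a log2 difference of -2.55 ± 0.22 (SE; adjusted p = 3.13e-06).

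**Figure D1:**
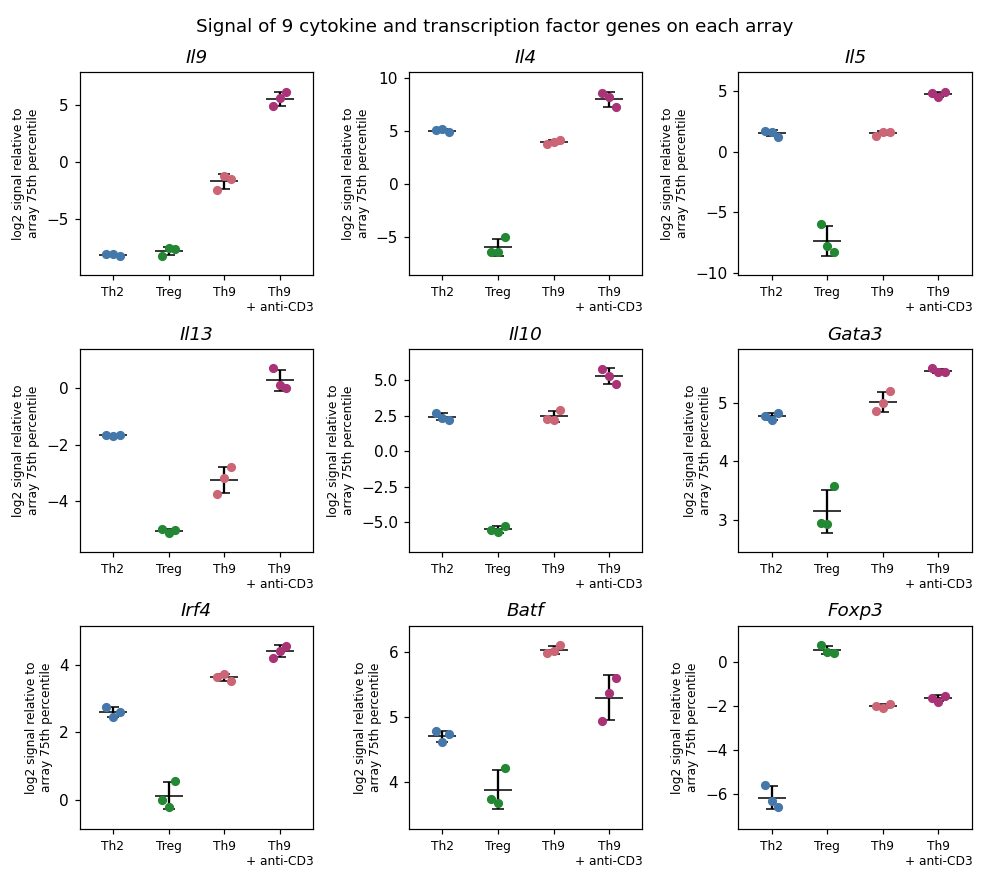
Log2 signal relative to the array's 75th percentile (vertical axis) for 9 genes on each of the 12 arrays, grouped by culture (horizontal axis); points are arrays, the long bar is the group mean and the short bars are 1 SD either side. Il9 is near -8 in Th2 and Treg cells, at -1.69 in Th9 cells and at 5.52 after anti-CD3. Il4, Il5 and Il10 lie far above the Treg level in both Th2 and Th9 cells.

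Th9 cultures differed from Th2 cultures by the added TGF-β. Apart from Il9, the genes with the largest increases in Th9 cells included Gpr15, a homing receptor of the gut, at least 14.5-fold higher (adjusted p = 9.08e-06). Il1rn, which encodes the IL-1 receptor antagonist, was at least 12.5-fold higher (adjusted p = 0.000118) and Erg, an ETS family transcription factor gene, at least 8.03-fold higher (adjusted p = 4.77e-07). The largest decreases included those of Sln, which encodes sarcolipin, a regulator of the calcium pump of muscle, with a log2 difference of -6.10 ± 0.44 (SE, n = 3 per group; adjusted p = 1.62e-05). Mlana, a melanocyte antigen gene, was at least 9.33-fold lower (adjusted p = 8.35e-07). Aldh1a3, an enzyme of retinoic acid synthesis, was at least 7.36-fold lower (adjusted p = 1.26e-06) and Clu, the extracellular chaperone clusterin, at least 9.7-fold lower (adjusted p = 0.00011).

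The Th2 cytokine genes Il5, Il10 and Il4 were not called between Th9 and Th2 cells. The log2 difference, Th9 minus Th2, was 0.02 ± 0.47 (SE) for Il5 (adjusted p = 0.981), 0.02 ± 0.28 for Il10 (adjusted p = 0.972) and -1.07 ± 0.40 for Il4 (adjusted p = 0.0914). Under the slide block the values were 1.89 (adjusted p = 0.0749) for Il5, 0.82 (adjusted p = 0.615) for Il10 and -0.60 (adjusted p = 0.819) for Il4. The Il4 difference passed the threshold when only the 6 arrays compared were fitted (adjusted p = 0.00516), and its adjusted p over all alternatives ranged from 0.00398 to 0.819. Il13 was lower in Th9 cells by a log2 difference of -1.57 ± 0.23 (adjusted p = 0.00125; -1.08, adjusted p = 0.436, with the slide as a block). Gata3, the transcription factor gene of Th2 cells, differed by 0.25 ± 0.16 (adjusted p = 0.336). Batf and Irf4, which encode partner transcription factors of activated T cells, were higher in Th9 cells by 1.32 ± 0.18 (adjusted p = 0.000882) and 1.03 ± 0.18 (adjusted p = 0.00423). Under the slide block those differences were 0.67 (adjusted p = 0.524) and 0.58 (adjusted p = 0.674).

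In all, limma called 1391 genes higher and 1658 lower in Th9 than in Th2 cells, 611 and 506 of them by at least 2-fold. Among the 18 tested Th9 genes, 7 were higher and 3 lower (8 and 3 adjusted over the list alone; camera adjusted p = 0.00426; adjusted p = 0.191 with an estimated correlation). They included Ahr, which encodes the aryl hydrocarbon receptor (2.97 ± 0.29), and Pparg, a nuclear receptor gene that was lower in Th9 cells (-2.67 ± 0.24, adjusted p = 5.63e-05). Of 29 TGF-β response genes, 8 were higher and 5 lower (11 and 6 adjusted over the list alone; camera adjusted p = 0.0422; adjusted p = 0.63 with an estimated correlation). Examples are Itgae, the integrin chain CD103 (3.84 ± 0.37, adjusted p = 9.88e-05), and Ccn2, connective tissue growth factor, at least 11.9-fold higher (adjusted p = 9.97e-05). With its Th2 probe at background, the fitted Ccn2 difference was 3.97 ± 0.39 without and 3.12 ± 0.95 with the slide as a block, where the larger error ended its call (adjusted p = 0.168). The camera call of the TGF-β list was lost with 6 of the alternatives, among them the omission of Th2 array 2 (adjusted p = 0.0776), Th2 array 3 (0.0692) or Th9 array 1 (0.155). Of 11 Th17 genes, 4 were higher and none lower (5 and 0 adjusted over the list alone; camera adjusted p = 0.00426, and adjusted p = 0.343 with an estimated correlation). With the slide as a block that list's adjusted p was 0.142, and its median log2 difference was 0.39 instead of 0.46. Of 24 Treg genes, 7 were higher and 5 lower (the same counts adjusted over the list alone; camera adjusted p = 0.55). Nt5e, the ectoenzyme CD73, was higher by 3.67 ± 0.27 (adjusted p = 1.85e-05).

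Ribosome biogenesis genes were lower in Th9 than in Th2 cells for 6 of 17 members and higher for none (13 and 0 adjusted over the list alone; camera adjusted p = 0.00114; adjusted p = 0.939 with an estimated correlation). Polr1b, a subunit of RNA polymerase I, had a difference of -1.17 ± 0.24 (adjusted p = 0.00891), and Dkc1, the pseudouridine synthase dyskerin, one of -0.89 ± 0.19 (adjusted p = 0.00991). Under the slide block the list's median log2 difference was 0.07 (adjusted p = 0.512), Polr1b stood at -0.09 (adjusted p = 0.972) and Dkc1 at -0.27 (adjusted p = 0.872). B cell markers were higher in Th9 than in Th2 cells for 3 of 10 and lower for none (4 and 0 adjusted over the list alone; camera adjusted p = 0.00536, and adjusted p = 0.63 with an estimated correlation; 0.0563 without the arrays numbered 3). Ebf1, a transcription factor of B cell commitment, was higher by 1.66 ± 0.30 (adjusted p = 0.00414; 1.11, adjusted p = 0.461, with the slide as a block). The other called members were Fcrla and Cd79b. Fcrla lost its call with normexp background correction (0.24, adjusted p = 0.203) and with the slide as a block (1.83, adjusted p = 0.173). Cd79b (0.95, adjusted p = 0.0496) lost its call when any 1 of the 6 arrays was left out.

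The lists of Th2 genes (5 higher and 5 lower of 27, 6 and 6 adjusted over the list alone), IL-4 and STAT6 response genes (2 and 2 of 16, 3 and 2 adjusted over the list alone), T cell cytokines (5 and 7 of 30, 8 and 9 adjusted over the list alone), early TCR response genes (5 and 9 of 36, 7 and 10 adjusted over the list alone) and Th1 genes (2 and 6 of 20, 3 and 7 adjusted over the list alone) moved both ways. Their camera adjusted p lay between 0.493 and 0.906. Ccr8, a chemokine receptor of Th2 and Treg cells, was higher by 2.04 ± 0.16 (adjusted p = 2.58e-05). Foxo1, a transcription factor of resting T cells, was higher as well (1.80 ± 0.10, adjusted p = 4.19e-06). Limma called 0 of 27 cell cycle genes (2 at an unadjusted p under 0.05), 0 of 19 glycolysis genes (2), 0 of 11 myeloid and dendritic cell markers (3) and 0 of 5 mast cell and basophil markers (0), also when adjusted over the list alone. Cholesterol synthesis genes were higher for 1 and lower for 2 of 20, and interferon-stimulated genes for 2 and 5 of 21 (3 and 6 adjusted over the list alone). Chemokines (1 and 3 of 13), homing receptors (3 and 4 of 18), naive and resting T cell genes (4 and 2 of 18), pan T cell markers (0 and 1 of 12) and CD8 T cell and NK cell markers (2 and 0 of 8) did not pass either, and their counts adjusted over the list alone were the same.

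No slide held both Th9 and Th2 arrays. With the slide as a block limma called 188 genes higher and 129 lower. Of these 317 genes, 206 were called in the same direction without the block. Of the 3049 genes called without it, 94.9% kept their sign, while the median SE rose from 0.166 to 0.367. Il9 (adjusted p = 0.0211), Foxp3 (adjusted p = 0.012), Sln (-7.89, adjusted p = 0.00193), Itgae (5.38, adjusted p = 0.00709), Nt5e (3.71, adjusted p = 0.0402), Pparg (-3.31, adjusted p = 0.0225) and Ahr (3.62, adjusted p = 0.045) stayed called. In all, 24 of the 77 called genes that the naming rule gave stayed called. The number of genes called lower fell to 957, 886, 1086 and 969 without Th2 array 1, Th2 array 2, Th9 array 1 and Th9 array 2 respectively, and the number called higher fell to 849 without Th9 array 2.

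Th9 and Treg cultures both held TGF-β and differed by IL-4 and antibody against IFN-γ in the Th9 cultures and by antibody against IL-4 and later IL-2 in the Treg cultures. Il4, Il5, Il10, Il13 and Il24 were higher in Th9 cells. Il4 was higher by a log2 difference of 9.96 ± 0.40 (SE, n = 3 per group; adjusted p = 1.75e-08), with its probe well above background on 1 of 3 Treg arrays, and Il24 by 10.47 ± 0.20 (adjusted p = 2.94e-10). Il5 was at least 184-fold higher (adjusted p = 9.1e-08), and Il10, an inhibitory cytokine gene, was higher by 7.97 ± 0.28 (adjusted p = 8.63e-09), with 2 of 3 Treg arrays well above background. Il13 was higher by 1.79 ± 0.23 (adjusted p = 4.95e-05). Irf4 was higher by 3.52 ± 0.18, Batf by 2.15 ± 0.18 and Gata3 by 1.87 ± 0.16, each with an adjusted p of 3.3e-06 or below.

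Glycolysis genes were higher in Th9 than in Treg cells for 18 of 19 members and lower for none (18 and 0 adjusted over the list alone; camera adjusted p = 9.22e-11; adjusted p = 0.228 with an estimated correlation). Hk2, which encodes the first enzyme of the pathway, hexokinase 2, was higher by 4.42 ± 0.16 (adjusted p = 1.03e-08), and Slc16a3, which encodes a lactate exporter, by 3.74 ± 0.23 (adjusted p = 3.01e-07). Cell cycle genes were higher for 20 of 27 and lower for none (20 and 0 adjusted over the list alone; camera adjusted p = 0.000141; adjusted p = 0.483 with an estimated correlation). The mitotic kinase gene Aurkb was higher by 1.54 ± 0.24 (adjusted p = 0.000208). Cholesterol synthesis genes were higher for 15 of 20 and lower for none (15 and 0 adjusted over the list alone; camera adjusted p = 0.000141; adjusted p = 0.382 with an estimated correlation). Fdps, the farnesyl diphosphate synthase gene, was higher by 2.56 ± 0.20 (adjusted p = 1.6e-06) and Lss, which encodes lanosterol synthase, by 2.48 ± 0.14 (adjusted p = 1.2e-07).

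All 21 interferon-stimulated genes were lower in Th9 than in Treg cells (all 21 also adjusted over the list alone; camera adjusted p = 3.63e-08; adjusted p = 0.236 with an estimated correlation). Rsad2, the antiviral enzyme viperin, had a difference of -5.88 ± 0.42 (adjusted p = 7.8e-07), and Oasl2 one of -6.63 ± 0.50 (adjusted p = 1.17e-06; -5.95 without Treg array 3). Naive and resting T cell genes were lower for 13 of 18 and higher for 2 (13 and 2 adjusted over the list alone; camera adjusted p = 0.000887; adjusted p = 0.236 with an estimated correlation). Tcf7, a transcription factor of naive T cells, stood at -3.76 ± 0.12 (adjusted p = 5.65e-09). In the same arrays, markers of B cells were lower in Th9 than in Treg cells for 9 of 10 and higher for none (9 and 0 adjusted over the list alone; camera adjusted p = 0.000141, and adjusted p = 0.228 with an estimated correlation), with Fcrla at -5.96 ± 0.22 (adjusted p = 1.07e-08) and Blk at -4.64 ± 0.23 (adjusted p = 5.43e-08). Ms4a1 (-5.25 ± 0.79, adjusted p = 0.000175) and Pax5 (-4.01 ± 0.62, adjusted p = 0.000221) were lower too, but under the slide block they stood at -1.57 (adjusted p = 0.054) and -1.39 (adjusted p = 0.116). The blocked values are reached through stimulated array 3, the only one on slide 3. For Ms4a1 the difference between Th2 and Treg hardly moved, from -5.21 to -5.37 within slide 1. Slide 3 and stimulated array 3 cannot be told apart as the source of the shift. Myeloid and dendritic cell markers were lower for 7 and higher for 2 of 11 (the same counts adjusted over the list alone; camera adjusted p = 0.0819), and pan T cell markers were lower for 7 of 12 and higher for none (7 and 0 adjusted over the list alone; camera adjusted p = 0.0127; adjusted p = 0.382 with an estimated correlation). Among them Cd5, a surface regulator of TCR signalling, stood at -1.93 ± 0.14 (adjusted p = 8.96e-07) and Cd3d, a chain of the TCR complex, at -0.91 ± 0.11 (adjusted p = 3.92e-05).

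Th2 genes were higher in Th9 than in Treg cells for 21 of 27 and lower for 1 (21 and 1 adjusted over the list alone; camera adjusted p = 1.52e-06; adjusted p = 0.053 with an estimated correlation). IL-4 and STAT6 response genes were higher for 13 of 16 and lower for none (13 and 0 adjusted over the list alone; camera adjusted p = 9.79e-06, and adjusted p = 0.053 with an estimated correlation), among them Nfil3, a transcription factor gene (5.67 ± 0.21, adjusted p = 1.07e-08). Th9 genes were higher for 11 of 18 and lower for 3 (11 and 3 adjusted over the list alone; camera adjusted p = 0.000887; adjusted p = 0.053 with an estimated correlation). Ccr6, the receptor of the chemokine CCL20, was lower in Th9 cells (-6.60 ± 0.29, adjusted p = 3.34e-08). T cell cytokines were higher for 14 and lower for 5 of 30 (14 and 5 adjusted over the list alone; camera adjusted p = 0.00516; adjusted p = 0.359 with an estimated correlation). TGF-β response genes were higher for 15 and lower for 7 of 29 (15 and 7 adjusted over the list alone; camera adjusted p = 0.0156; adjusted p = 0.248 with an estimated correlation). Ccn2 was at least 13.0-fold higher (adjusted p = 1.51e-06) and Id3, an inhibitor of DNA binding, was lower (-5.47 ± 0.19, adjusted p = 7.66e-09). The list of Treg genes was higher in Th9 than in Treg cells for 15 of 24 and lower for 3 (15 and 4 adjusted over the list alone; camera adjusted p = 0.00561; adjusted p = 0.242 with an estimated correlation). The higher members included Tnfrsf9, the costimulatory receptor 4-1BB (5.14 ± 0.15), Rgs1, a regulator of G protein signalling (2.94 ± 0.17), and Gzmb, the protease granzyme B (2.65 ± 0.54), while Foxp3 was lower.

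The remaining lists did not pass the threshold between Th9 and Treg cells (camera adjusted p from 0.147 to 0.511). Chemokines were higher for 2 and lower for 7 of 13, homing receptors for 6 and 10 of 18, Th17 genes for 5 and 2 of 11, early TCR response genes for 14 and 12 of 36, mast cell and basophil markers for 0 and 2 of 5, and CD8 T cell and NK cell markers for 2 and 1 of 8, each with the same counts adjusted over the list alone. Th1 genes were higher for 5 and lower for 10 of 20 (5 and 11 adjusted over the list alone), and ribosome biogenesis genes for 6 and 4 of 17 (6 and 3 adjusted over the list alone). Cxcr3, a Th1 chemokine receptor gene, was lower in Th9 cells by a log2 difference of -5.20 ± 0.40 (adjusted p = 1.18e-06). In all, limma called 5154 genes higher and 6320 lower, 2760 and 3003 of them by at least 2-fold. No slide held both groups, and with the slide as a block the counts were 3157 and 3528, with 6299 genes called in the same direction in both fits and 4 in opposite directions. Under that block 85 of 95 called genes of the naming rule stayed called, and some sizes moved: Gzmb stood at 4.76, Cxcr3 at -3.66, Ccr6 at -7.72, Slc16a3 at 2.96, Il4 at 10.90 and Il10 at 8.80.

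**Figure D2:**
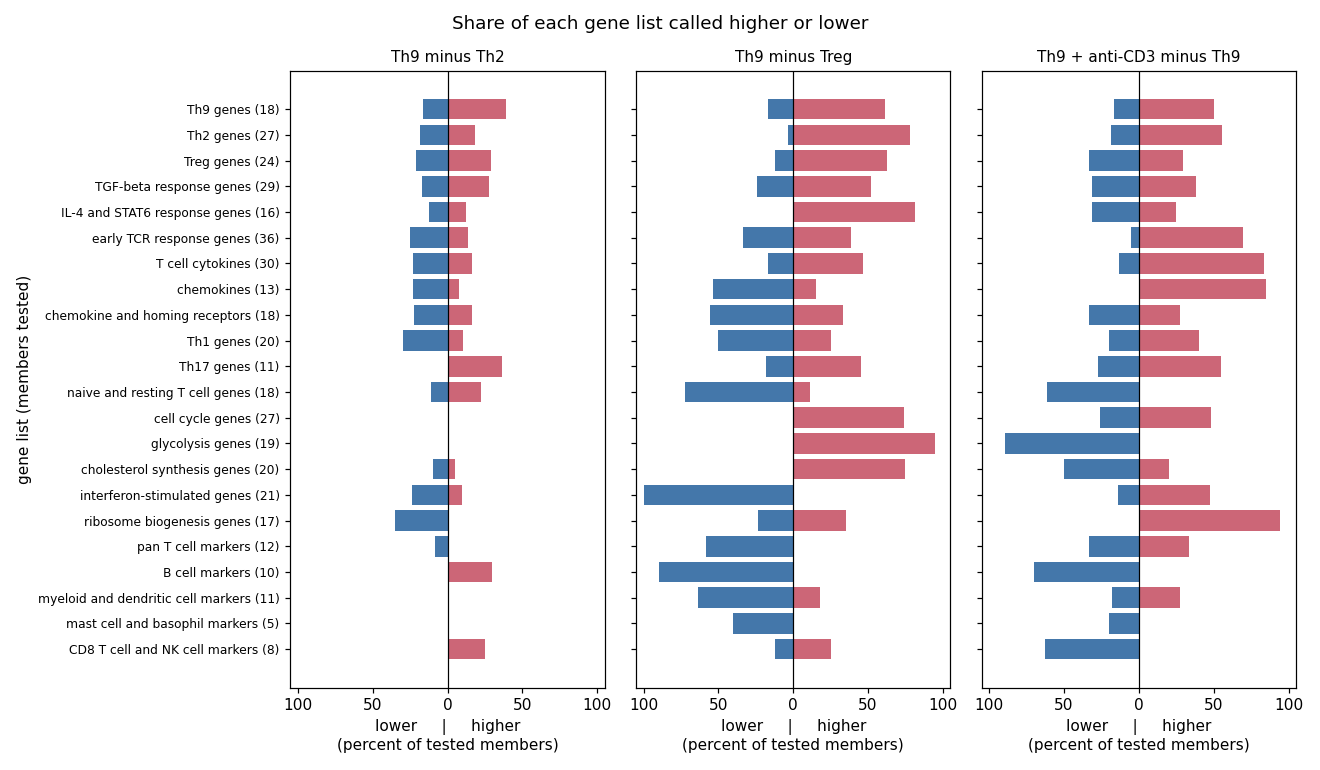
Percent of the tested members of each gene list (vertical axis, number tested in brackets) called higher (right, red) or lower (left, blue) at an adjusted p under 0.05, in 3 comparisons. All 21 interferon-stimulated genes were lower in Th9 than in Treg cells, 18 of 19 glycolysis genes were higher, and 16 of 17 ribosome biogenesis genes were higher after anti-CD3.

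A set of 755 genes was higher in Th9 cells than in both Th2 and Treg cells, 382 of them by at least 2-fold in each comparison, and 772 were lower than in both, 176 of them by at least 2-fold. Among those with the largest differences were Il9, Gad2, which encodes a glutamate decarboxylase, and Erg. Gad2 was higher than in Th2 cells by 5.31 ± 0.33 (adjusted p = 7.99e-06), with 2 of 3 Th2 arrays well above background, and at least 53.5-fold higher than in Treg cells (adjusted p = 3.38e-08). Il17rb, a subunit of the receptor for IL-25, was at least 23.8-fold higher than in Th2 cells (adjusted p = 4.15e-05) and at least 25.8-fold higher than in Treg cells (adjusted p = 2.24e-06). With its Th2 probe at background, the fitted Il17rb difference from Th2 was 5.43 ± 0.45 without and 3.77 ± 0.92 with the slide as a block, where it was not called (adjusted p = 0.0897). Epsti1, an interferon-induced gene, was lower than in both (-2.68 ± 0.18 against Th2, adjusted p = 1.15e-05, and -4.37 ± 0.18 against Treg, adjusted p = 2.4e-08). Nqo2, a quinone reductase gene, was also lower (-2.69 ± 0.33, adjusted p = 0.000412, and -3.10 ± 0.33, adjusted p = 1.28e-05). Under the slide block Nqo2 stood at -4.27 against Th2 and -4.32 against Treg, Epsti1 at -3.56 against Th2 and Gad2 at 4.18 against Th2.

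Independent lists of the same sizes would share 400 genes in the higher direction and 585 in the lower. In data simulated with no difference between groups 0 genes were called in both comparisons. With no true difference almost no gene passes the adjusted threshold in either comparison, so that value cannot be set against the observed overlap. Mixed directions were found for 318 genes (490 if independent) higher than in Th2 and lower than in Treg, and for 432 (477 if independent) lower than in Th2 and higher than in Treg. Both comparisons share the 3 Th9 arrays, so part of the excess may come from them. With the slide as a block 114 genes were higher and 66 lower than in both. Without Th9 array 2 the counts were 481 and 418, and the lower count was 449 without Th2 array 1 and 415 without Th2 array 2.

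**Figure D3:**
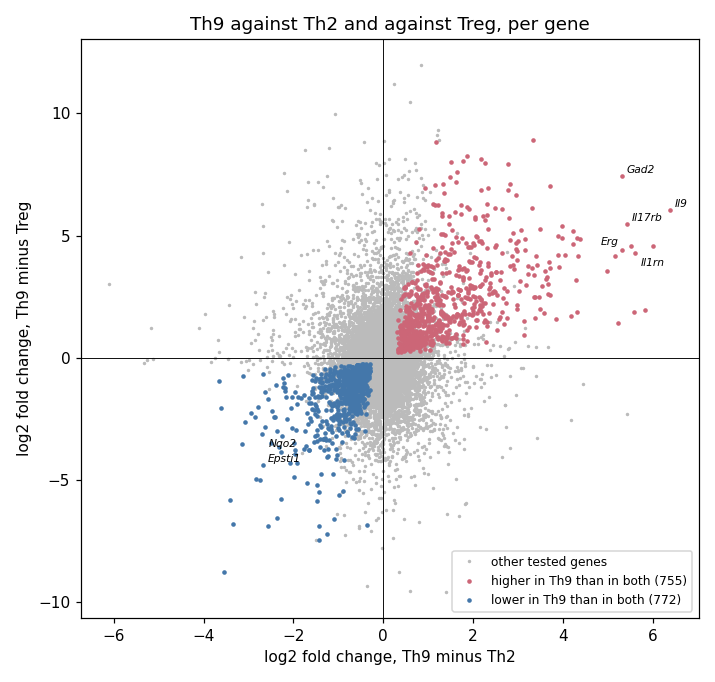
Log2 difference of each tested gene between Th9 and Th2 (horizontal axis) and between Th9 and Treg (vertical axis); each point is a gene. The 755 genes called higher in Th9 than in both are red, the 772 called lower than in both are blue, and Il9, Gad2, Il17rb, Erg, Il1rn, Epsti1 and Nqo2 are labelled.

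Where Th9 cells lie between Th2 and Treg cells was measured on 5649 genes that differed at least 2-fold between Th2 and Treg, a choice in which the Th9 arrays entered only through the variance of the joint fit. On a scale from 0 (Treg) to 1 (Th2), the median position of the Th9 mean was 0.937, with quartiles of 0.74 and 1.12, and 5096 genes (90.2%) lay nearer to Th2. Limma placed Th9 beyond Th2 for 443 genes and beyond Treg for 30. A further 4128 genes differed from Treg and not from Th2, and 206 differed from Th2 and not from Treg. Foxp3 was at least 82.3-fold lower in Th2 than in Treg cells (adjusted p = 6.48e-09) and its Th9 level lay between. The genes are not independent of each other. With the slide as a block the median position was 0.879.

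Restimulation of Th9 cells with anti-CD3 for 6 h was compared with unstimulated Th9 cells. Cytokine and chemokine genes were among those that rose most. Il9 rose by a log2 difference of 7.22 ± 0.36 (SE, n = 3 per group; adjusted p = 1.04e-07), a 149-fold increase. Il4 rose by 4.06 ± 0.40 (adjusted p = 6.2e-06) and Il13 by 3.51 ± 0.23 (adjusted p = 3.69e-07). Il5 rose by 3.23 ± 0.47 (adjusted p = 0.000114) and Il10 by 2.83 ± 0.28 (adjusted p = 6e-06). Il3 rose at least 1750-fold (adjusted p = 7.59e-08; at least 3020-fold without stimulated array 3). Ccl3, a chemokine of activated T cells and macrophages, rose at least 3030-fold (adjusted p = 2.39e-07; at least 6460-fold without stimulated array 3) and Areg, which encodes the growth factor amphiregulin, at least 37.1-fold (adjusted p = 7.24e-08). Ifng, the Th1 cytokine gene, rose by 6.82 ± 0.80 (adjusted p = 2.24e-05), with levels of 7.02 ± 2.14 (SD) after and 0.20 ± 0.41 before. Stimulated array 3, the only one on slide 3, stood apart, with Ifng at 4.56 against 8.39 and 8.12 on arrays 1 and 2. The same array was the lowest stimulated array for Gzmb (4.995 against 7.351 and 7.204) and for Cd8a and Cd8b1, given below. That array was also lowest for the cytokine genes Il3 (3.09 against 5.86 and 5.06) and Il2 (-0.37 against 1.09 and 1.12). It was highest for Il9 (6.11 against 4.87 and 5.59) and Il5 (4.93 against 4.85 and 4.54). The lower Ifng signal there thus went with CD8 T cell genes and with some induced cytokine genes. Which cells the Ifng transcripts came from was not tested. The Ifng difference was 8.06 without that array and 4.36 within slide 3, where Il4 stood at 3.28 and Tbx21 at 2.26. Tbx21, the Th1 transcription factor gene, rose by 3.18 ± 0.34 (adjusted p = 1.2e-05).

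T cell cytokines rose for 25 and fell for 4 of 30 (25 and 4 adjusted over the list alone; camera adjusted p = 9.06e-06; adjusted p = 0.427 with an estimated correlation). Tgfb3, a TGF-β gene, fell by 6.86 ± 0.28 on the log2 scale (adjusted p = 5.58e-08). Early TCR response genes rose for 25 and fell for 2 of 36 (25 and 3 adjusted over the list alone; camera adjusted p = 7.06e-05, and adjusted p = 0.427 with an estimated correlation), with Fosl1, an AP-1 subunit gene, rising by 6.61 ± 0.28 (adjusted p = 6.21e-08). Chemokines rose for 11 of 13 and fell for none (11 and 0 adjusted over the list alone; camera adjusted p = 0.000145; adjusted p = 0.427 with an estimated correlation). Ribosome biogenesis genes rose for 16 of 17 and fell for none (16 and 0 adjusted over the list alone; camera adjusted p = 5.16e-08; adjusted p = 0.427 with an estimated correlation). Nolc1, a nucleolar protein gene, rose by 4.32 ± 0.22 (adjusted p = 1.06e-07) and Rrp9, a ribosomal RNA processing gene, by 4.01 ± 0.20 (adjusted p = 1.04e-07).

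Glycolysis genes fell for 17 of 19 and rose for none (17 and 0 adjusted over the list alone; camera adjusted p = 3.28e-06; adjusted p = 0.427 with an estimated correlation). Slc2a3, a glucose transporter gene, changed by -4.65 ± 0.22 (adjusted p = 1.02e-07). Pdk1, which encodes a kinase that inhibits pyruvate dehydrogenase, changed by -3.91 ± 0.23 (adjusted p = 2.1e-07) and Pfkm, a phosphofructokinase gene, by -3.70 ± 0.20 (adjusted p = 1.44e-07). Naive and resting T cell genes fell for 11 of 18 and rose for none (11 and 0 adjusted over the list alone; camera adjusted p = 0.00234, and adjusted p = 0.427 with an estimated correlation), with Nsg2 at -3.85 ± 0.13 (adjusted p = 2.66e-08). B cell markers fell for 7 of 10 and rose for none (7 and 0 adjusted over the list alone; camera adjusted p = 0.00954, and adjusted p = 0.427 with an estimated correlation; 0.0897 without the arrays numbered 3). Ighm, the immunoglobulin µ heavy chain gene, changed by -2.15 ± 0.33 (adjusted p = 0.000189) and Cd79b, a B cell receptor chain gene, by -2.60 ± 0.30 (adjusted p = 1.84e-05), and within slide 3 they stood at -3.12 and -3.33. The camera call of this list was also lost with normexp background correction (adjusted p = 0.0526). When probes had to be above background on all arrays, it and the call of the chemokines were lost (adjusted p = 0.158 for each).

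The other lists did not pass the threshold (camera adjusted p from 0.153 to 0.955). Th9 genes rose for 9 and fell for 3 of 18 (9 and 3 adjusted over the list alone), and Il17rb fell by 5.14 ± 0.45 on the log2 scale (adjusted p = 2.93e-06), with 1 of 3 stimulated arrays well above background. Th2 genes rose for 15 and fell for 5 of 27, Th17 genes for 6 and 3 of 11, Th1 genes for 8 and 4 of 20, and Treg genes for 7 and 8 of 24. TGF-β response genes rose for 11 and fell for 9 of 29, cell cycle genes for 13 and 7 of 27, and interferon-stimulated genes for 10 and 3 of 21. The counts adjusted over the list alone were the same. Among cell cycle genes, Mcm2, a subunit of the replicative helicase, rose by 1.83 ± 0.25 (adjusted p = 7.77e-05) and Ccnb2, a mitotic cyclin gene, changed by -2.24 ± 0.30 (adjusted p = 7.21e-05). Isg15, an interferon-induced ubiquitin-like protein gene, rose by 3.37 ± 0.32 (adjusted p = 5.33e-06). Cholesterol synthesis genes rose for 4 and fell for 10 of 20 (5 and 10 adjusted over the list alone), IL-4 and STAT6 response genes for 4 and 5 of 16 (3 and 5 adjusted over the list alone) and homing receptors for 5 and 6 of 18 (5 and 6 adjusted over the list alone). CD8 T cell and NK cell markers fell for 5 of 8 and rose for none (5 and 0 adjusted over the list alone; camera adjusted p = 0.153). Part of this fall lay in stimulated array 3. There Cd8b1, a CD8 chain gene, stood at 1.29 against 3.38 on each of the other stimulated arrays, and Cd8a, which was not called, at -2.23 against 2.47 and 2.29. Without that array the Cd8b1 difference was -0.80 instead of -1.50 and still called, but its call was lost when only the 6 arrays compared were fitted (adjusted p = 0.0556). Klrk1, an NK cell receptor gene, had a difference of -1.52 (adjusted p = 0.0297), and -0.83 (adjusted p = 0.0938) without that array. Its call was also lost without Th9 array 1, 2 or 3, with the replicate block (adjusted p = 0.0501) and when only the arrays compared were fitted (adjusted p = 0.0502). Pan T cell markers rose for 4 and fell for 4 of 12, myeloid and dendritic cell markers for 3 and 2 of 11, and mast cell and basophil markers for 0 and 1 of 5.

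Among lineage transcription factor genes, Irf4 rose by 0.77 ± 0.18 (adjusted p = 0.00372; 0.0641 after quantile normalization) and Gata3 by 0.53 ± 0.16 (adjusted p = 0.0151; 0.268 after quantile normalization, and 0.45 with adjusted p = 0.0566 without Th9 array 1). Within slide 3 the Gata3 difference was 0.51 (adjusted p = 0.102). Batf changed by -0.73 ± 0.18 (adjusted p = 0.00429), and within slide 3 by -0.43 (adjusted p = 0.154). Values within slide 3 rest on 1 stimulated array, which is assumed to vary like the arrays of the other groups. Foxp3 differed by 0.35 ± 0.22 (adjusted p = 0.193; 0.0402 when only the 6 arrays compared were fitted, and 0.00914 with normexp background correction). In all, limma called 5943 genes up and 5475 down, 3181 and 2976 of them by at least 2-fold. Within slide 3, which held 1 stimulated and 3 unstimulated arrays, the counts under that assumption were 4816 and 4247.

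Of the 755 genes higher in Th9 cells than in both other cultures, 81 rose after restimulation, 517 fell and 157 were not called. The share that fell, 68.5%, compares with a median of 30.6% (range 25.2 to 35.2%) in 1000 sets of genes matched on mean level. Il17rb fell, while Il9 rose. Of the 772 genes lower in Th9 cells than in both, 439 (56.9%) rose, against 35.4% in matched sets, and 156 fell. In data simulated with no change after stimulation the shares were 0%. With no gene changed almost none passes the adjusted threshold, so this value was fixed in advance. The Th9 arrays are shared between these comparisons, and how much that adds to the observed shares was not measured. With the slide as a block 63.2% of the Th9-high genes fell.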

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

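The alternative that leaves out all arrays numbered 3 was chosen after the data were seen, because the fourth principal component (2% of the variance) set those arrays apart. Over all alternatives, 355 results of named genes gave 7320 values. Of these, 7124 kept their side of the threshold, with the same direction wherever they were called, 186 lost the threshold, 5 gained it and 5 that had been called changed sign. The 7124 include all 355 values under the 2-fold requirement and all 355 under the adjusted p of 0.01. Those were judged at the main threshold on the main fit, so they could not change and say nothing of robustness. All 355 values under the random slide block were kept too, where the estimated correlation within slides was only -0.0027. Of 570 values of gene lists, 553 kept their side of the threshold, 16 lost the threshold and 1 changed sign. Il9 and Foxp3 kept their calls between Th9 and Th2 in every alternative that tested them, with an adjusted p of at most 0.0211 for Il9 and 0.012 for Foxp3. The filter for probes above background on all arrays leaves out the probes used for them, which were at background in Th2 cells.

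In the fit with the slide as a fixed block the counts were 188 higher and 129 lower for Th9 against Th2, 3157 and 3528 for Th9 against Treg, and 114 higher and 66 lower in Th9 than in both. The median position of Th9 was 0.879. Of the 114 genes higher in both in that fit, 63.2% fell after stimulation, a share that the shared stimulated array 3 can raise. Csf2 (0.063, adjusted p = 0.987), Ccl3 (0.14, 0.98), Ccl4 (0.98, 0.529) and Cxcl3 (-0.45, 0.902) changed sign between Th9 and Th2, as did Xcl1 (0.33, 0.771) between Th9 and Treg and the ribosome biogenesis list between Th9 and Th2 (median 0.069, 0.512). The block leaves Th9 joined to Th2 and Treg only through other slides, which raised the median SE from 0.166 to 0.367 against Th2 and to 0.293 against Treg. The chain passes through stimulated array 3, the only stimulated array on slide 3. Its difference from unstimulated Th9 there was 10.97 for Ccl3, 7.49 for Ccl4, 5.21 for Csf2 and 5.86 for Xcl1. Over all stimulated arrays those differences were 13.15, 9.51, 7.24 and 8.38. The lower signal on that array moves the blocked Th9 value up, as these genes moved. Slide 3 and that array cannot be told apart as its source. Nor was an effect of its number separated, although the fourth principal component set the arrays numbered 3 apart in every group. The cause for Cxcl3 and the ribosome list was not tested.

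Requiring a 2-fold difference left 611 higher and 506 lower for Th9 against Th2, 2760 and 3003 for Th9 against Treg, 3181 and 2976 after stimulation, 2813 and 2836 for Th2 against Treg, and 382 and 176 for both. An adjusted p under 0.01 left 634 and 597 for Th9 against Th2, and 368 and 255 for both. These alternatives are stricter by construction. The median position was 0.949 with normexp background correction, 0.947 with quantile normalization and 0.927 without the arrays numbered 3. Without those arrays, 73.0% of the Th9-high genes fell. The causes were not tested. Median scaling moved the median log2 difference of all genes between Th2 and Treg from -0.08 to 0.02. It also turned the balance of calls there, from 5249 higher and 5997 lower to 5773 and 5093. After stimulation the balance turned with quantile normalization, from 5943 higher and 5475 lower to 5627 and 5815, and with the deposited log2 table, to 5625 and 5816.

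Leaving out each array in turn gave 849 to 1255 genes higher and 886 to 1497 lower for Th9 against Th2. The lower count was 957 without Th2 array 1, 886 without Th2 array 2, 1086 without Th9 array 1 and 969 without Th9 array 2, and the higher count was 849 without Th9 array 2. Counts were 481 to 869 higher in both (481 without Th9 array 2) and 415 to 873 lower in both (449 and 415 without Th2 arrays 1 and 2, 418 without Th9 array 2). The position ranged from 0.923 to 0.948 and the share of Th9-high genes that fell from 62.4 to 70.0%. The counts for both rose to 869 and 873 without Treg array 3, and those for Th9 against Th2 to 1605 and 2069 without all arrays numbered 3. The causes of these changes were not tested.

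Deviations of same-numbered arrays from their group means correlated at 0.048 to 0.141 for Th9 and Treg, 0.095 to 0.209 for stimulated and unstimulated Th9, and -0.007 to 0.025 for Th2 and Treg. With the replicate number as a block the counts were 1402 and 1683 for Th9 against Th2, 5174 and 6360 for Th9 against Treg, and 6024 and 5574 after stimulation. Gene list tests were not run for the random slide block, the arrays compared alone, the intensity trend, the stricter thresholds or the deposited log2 table. Signal over background limits what can be said of dim genes: 59.8 to 63.7% of probes were well above background on an array.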

Other observations

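The test on macrophage genes was chosen after the result it concerns had been seen.

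The comparison of Th2 with Treg cells uses the same 3 Treg arrays as that of Th9 with Treg cells. Limma called 5249 genes higher and 5997 lower in Th2 than in Treg cells. Pparg, a nuclear receptor gene, was higher in Th2 cells by a log2 difference of 6.98 ± 0.24 (SE, n = 3 per group; adjusted p = 6.6e-09), and Hk2 by 4.80 ± 0.16. Il4 was higher by 11.03 ± 0.40 (adjusted p = 9.59e-09), with 1 of 3 Treg arrays well above background. Ccr6 was lower (-7.06 ± 0.29), as was Tcf7 (-3.65 ± 0.12). Glycolysis genes were higher for 18 of 19 (camera adjusted p = 4.48e-10; adjusted p = 0.182 with an estimated correlation) and cholesterol synthesis genes for 18 of 20 (5.61e-06; 0.34). Th2 genes were higher for 19 and lower for 2 of 27 (1.1e-05; 0.111), IL-4 and STAT6 response genes for 12 and 2 of 16 (4.96e-05; 0.111) and cell cycle genes for 19 and 0 of 27 (4.62e-05; 0.479). Ribosome biogenesis genes were higher for 12 and lower for 1 of 17 (0.00912; 0.527), T cell cytokines for 15 and 6 of 30 (0.00912; 0.407), Treg genes for 13 and 5 of 24 (0.0193; 0.34) and Th9 genes for 10 and 3 of 18 (0.0314; 0.182). All 21 interferon-stimulated genes (4.85e-08; 0.217), all 10 B cell markers (1.39e-05; 0.182), 14 of 18 naive and resting T cell genes (2.87e-05; 0.182) and 8 of 12 pan T cell markers (0.0193; 0.45) were lower in Th2 cells. The call of the Th9 genes was lost when probes had to be above background on all arrays (adjusted p = 0.175) and without the arrays numbered 3 (0.051). The call of the pan T cell markers was lost with the slide as a block (0.0502) and without the arrays numbered 3 (0.051). TGF-β response genes (12 higher and 9 lower of 29), early TCR response genes (15 and 9 of 36), chemokines (2 and 7 of 13), homing receptors (5 and 11 of 18), Th1 genes (4 and 11 of 20), Th17 genes (3 and 3 of 11), and markers of myeloid (2 and 7 of 11), mast (0 and 1 of 5) and CD8 T and NK cells (2 and 2 of 8) did not pass the threshold (camera adjusted p from 0.116 to 0.862). The counts adjusted over the list alone were 20 and 3 for Th2 genes, 14 and 5 for Treg genes, 22 and 0 for cell cycle genes, 13 and 9 for TGF-β response genes, 6 and 11 for homing receptors and 5 and 11 for Th1 genes, and the same for the other lists.

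B cell markers were higher in the Treg arrays than in those of Th9 (9 of 10) and Th2 cells (10 of 10). If B cells had remained in the Treg cultures, their abundant MHC class II transcripts should be higher too, and the median log2 difference over 6 such genes, none of them in another list, was 2.61 (SE 0.121) against Th9 and 3.82 (SE 0.29) against Th2. Cd74 stood at 5.11 in Treg, 2.37 in Th9 and 1.00 in Th2 cells, with H2-Ab1 as an exception at 5.23, 5.60 and 5.18. Macrophages stay open, since 5 macrophage genes, all of them also in the myeloid list, had a median difference of -0.17 against Th9 but went both ways (Adgre1 2.87 lower and Cd14 0.90 higher in Treg), while 7 of the 11 myeloid markers were higher in Treg cells. B cells are a candidate source, although the magnetic selection of naive CD4+ T cells would remove them. Dendritic cells and macrophages carry MHC class II too, so these genes do not single out B cells. A difference caused by the Treg culture itself was not tested and stays open.

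Between Th9 and Th2, which share no slide, differences between slides could produce calls. The Treg and stimulated Th9 arrays, which lie on more than 1 slide, give an estimate of the slide 3 minus slide 1 difference, and its slope on Th9 minus Th2 over 3047 called genes was 0.034 (95% interval 0.008 to 0.061), where slides as the whole cause would give 1. The interval came from resampling genes as if independent and leaves out the error of the slide estimate. That estimate rests on 1 stimulated array on slide 3 and 1 Treg array on slide 1, and mixes slide with array number. As far as these arrays stand for their slides, the slope argues against slides as the main source over these genes together. It does not settle single genes: with the slide as a block 94.9% of the 3049 genes kept their sign, while the median SE rose from 0.166 to 0.367. The 10 splits of 6 arrays into 3 and 3 are too few for a share under 0.05. In each comparison 1 of the 10 splits, the real one, gave as many genes: 3049 against a highest other of 1 for Th9 and Th2, 11474 against 0 for Th9 and Treg, 11418 against 1 after stimulation and 11246 against 0 for Th2 and Treg. Every other split mixes the cultures, so their difference enters the spread within groups and few calls were bound to follow. A slide difference between Th9 and Th2 would give the same contrast. These counts therefore decide nothing about the source of the calls.

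Of 100 splits of the 9 unstimulated arrays into 3 groups, 3 gave at least 755 genes higher in the first group than in both others, and 3 gave at least 772 lower, the real split included. The highest other counts were 5065 and 4282. Among the splits of the Th9 and Th2 arrays that part all 3 number pairs, as the real one does, the 3 others gave at most 1 gene, and the 6 that part 1 pair gave at most 0 (limma). All of these but the real split mix the cultures, so few calls were bound to follow there as well. The same holds for splits of the 9 arrays whose first group mixes cultures. The 2 larger splits have the 3 Treg arrays as the first group, which reflects how far Treg lies from the other cultures, a structure of the samples.

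Ahr was higher in Th9 than in Th2 cells, and so were its targets Ahrr (4.30 ± 0.45, adjusted p = 0.000165) and Cyp1a1 (3.62 ± 0.97, adjusted p = 0.0288). A wider response of the aryl hydrocarbon receptor could underlie this. The other targets on the list that were tested, Tiparp (-0.12, adjusted p = 0.67) and Nqo1 (0.06, adjusted p = 0.955), had a median log2 difference of -0.031 (SE 0.248), but Nqo1 was well above background on only 2 of 3 arrays in each group, and with 2 genes the question stays open.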
